A study of Canis lupus familiaris with 6 samples.

How the data were processed

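The series holds RNA sequencing of canine melanoma cell lines, per the labels: CMM2 and CMM12, each as 1 control library and 2 libraries of podoplanin KO lines numbered 1 and 2. RNA was purified with the RNeasy mini kit and libraries were made from 1 ug of total RNA with a NEBNext Ultra RNA kit, per the labels' protocols. STAR 2.7.3a, RSEM 1.3.3 and the build CanFam3.1 are named in the submitters' processing notes. The strand setting of the counting is not given in the sources used here, so reads of a gene and of an antisense partner cannot be told apart, and neither can reads of near-identical copies. Expected counts per gene, not scaled between libraries, were deposited by the authors for each library, per the file headers. TPM values, scaled for transcript length within each library, were deposited beside them, per the file headers. Each table lists genes by an Ensembl identifier, 18011 of them with a symbol and 12940 without. Those rows took 7.89% to 8.85% of the counts and stayed in the library sizes and tests under their identifiers, and 1975 rows share a symbol with another row, of which the one with the highest mean count stood for the symbol.

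Groups were taken from the titles and genotypes of the labels. The library totals were 10719884 counts in the CMM2 control, 11807835 in CMM2 KO 1, 10847887 in CMM2 KO 2, 11287633 in the CMM12 control, 10927552 in CMM12 KO 1 and 9732927 in CMM12 KO 2. At these depths 3 counts, the floor per library used for folds against groups at 0, correspond to 0.259 to 0.294 CPM. Intervals and floors cover counting error only. Expected counts were rounded to whole numbers, which changed 3.22% to 3.63% of the values in a library. No pair of libraries in a line agreed within sampling noise (chi-square per degree of freedom 17.3 to 72.2).

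The main test was edgeR 4.0.16 (glmQLFit and glmQLFTest with the default setting of the spread estimate) in R 4.3.3, with TMM factors, filterByExpr on the 4 groups and Benjamini-Hochberg adjustment at 0.05 over the 12270 genes kept. Standard errors were computed so that the squared ratio of a log2 fold change to its error is the quasi-likelihood F. The KO effect across lines and the contrast of CMM12 with CMM2 came from a model with additive line and genotype terms (3 residual degrees of freedom). The KO effect in each line and the difference of these effects came from a model of 4 group means (2 residual degrees of freedom), in which the spread comes from the KO pairs and the lone control of each line is assumed to vary like them, as is a KO library whose partner was left out. KO number 2 was set against number 1 in a model of line and number. The agreement of the lines was described by correlations across genes. Groups, models, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined.

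The 40 gene lists held 1161 different genes, of which 1009 were listed and 857 tested. They were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the lists, and per gene over the list alone. With an estimated correlation camera rests on the few residual degrees of freedom of the model, so a list can fail there without members that vary together. Counts adjusted over the list alone are summed over lists, so a gene of several lists can count more than once.

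The rule for named genes took PDPN and, among genes with a symbol, those with an adjusted p under 0.05, a mean of at least 1 CPM and every KO library on the same side of its line's control. Of these it took the 10 largest changes in each direction across lines, 8 in each line and between lines (there with every library of one line above every library of the other), and 5 for the difference between lines (without the condition on sides) and for the KO numbers. From each list it took up to 4 members with the smallest adjusted p, or the smallest unadjusted p where none passed, and it took every tested podoplanin partner. Because edgeR called at most 1 gene in the KO comparisons, the rule was also applied to DESeq2 calls there, a choice made after seeing the data. Other genes are named with the words that they were chosen after their values were seen.

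Alternatives fixed beforehand were the DESeq2 1.42.0 Wald test (adjusted p-values given as NA stayed NA, for 1190 genes in CMM12 and 1903 in the comparison of KO numbers), median-of-ratios factors, no low-count filter, a filter of at least 1 CPM in 2 libraries, a robust fit, unrounded values, glmTreat against a fold of 1.5, other model forms, and leaving out each library in turn. limma with a trend was run on log2(TPM + 1) and log2(TPM + 0.1), which understate the changes of low genes, over genes with a TPM of at least 1 in 1 library, and without that filter. Added after the data had been seen were the bias-adjusted form of the quasi-likelihood fit, whose counts were known when the default was kept, the list tests of the difference between lines and of the KO numbers, and list tests in each line without 1 KO library.

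Each test was run on simulated counts with 200 genes changed by known folds. The changed genes were picked above a minimum mean count and the libraries were drawn independently, so the shares may overstate the power in the real data. There PDPN, 5.15-fold lower across lines, was not called by edgeR (adjusted p 0.288). At 2-, 4- and 8-fold, edgeR recovered 28.4%, 82.1% and 93.9% of the changed genes across lines, among 12044 genes. The shares were 8.96%, 61.2% and 86.4% in CMM2 (12059 genes), 2.99%, 59.7% and 84.8% in CMM12 (12035 genes), 1.49%, 44.8% and 69.7% for the difference between lines (12057 genes), 44.8%, 83.6% and 97.0% for CMM12 against CMM2 (11235 genes) and 10.4%, 79.1% and 92.4% for the KO numbers (12040 genes). False calls exceeded the nominal share. edgeR made 12 false among 148 calls across lines, 12 of 116 in CMM2, 15 of 113 in CMM12, 35 of 112 for the difference, 11 of 161 between lines and 8 of 129 for the KO numbers. DESeq2 made 34 of 183, 31 of 147, 34 of 141, 35 of 115, 30 of 194 and 30 of 167 in the same order. When 1 simulated list, collagen and matrix, was shifted by 1 on the log2 scale across lines, it passed camera with an estimated correlation (adjusted p 0.014) and fry (0.016), and 0 other lists passed. With the preset correlation its adjusted p was 9.8e-57. Simulated genes were drawn independently, while this list had an estimated correlation of 0.164 in the real data. The simulation therefore does not show the power of these tests for members that vary together.

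No genome coordinates are given. Some list members are not reported here. Gene positions, splicing and the edited site of podoplanin were not analysed here.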

Results

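RNA was sequenced from CMM2 and CMM12, 2 canine melanoma cell lines, each as a control and as 2 knockout (KO) lines of podoplanin, numbered KO 1 and KO 2. That gave 6 libraries, 1 per control and per KO line. Podoplanin is a mucin-like membrane glycoprotein that binds ezrin-family proteins inside the cell and the platelet receptor CLEC-2 outside it. The libraries held 9732927 to 11807835 estimated counts each on the genes of the build CanFam3.1, of which 12270 had enough counts to be tested. The first principal component carried 69.9% of the variance and separated CMM2 from CMM12, and the following components carried 11.0% and 9.4%. On the second, CMM2 KO 2 (−45.4) and the CMM12 control (−36.3) lay together, apart from the other libraries (15.3 to 23.1). The second component therefore did not follow the genotype. On the third, the controls lay at −18.3 in CMM2 and −41.0 in CMM12. KO 1 lay at −11.8 and 5.09, and KO 2 at 32.0 and 34.0, in the same order of lines. In both lines the third component rose from control to KO 1 to KO 2. Whether it follows the genotype or the KO number was not tested. Of the 8660 genes at a mean of 10 or more CPM (counts scaled to the library size), the share that differed at least 2-fold was 1.06% between the CMM2 control and CMM2 KO 1. It was 6.74% between the CMM2 control and CMM2 KO 2 and 4.99% between both CMM2 KO lines, so CMM2 KO 2 stood apart in its line. In CMM12 the shares were 4.72% and 4.62% between the control and KO 1 and KO 2, and 3.37% between the KO lines. Nothing in the labels says that the libraries came from separate cultures or whether the KO lines are single clones, so p-values measure only the spread between these samples, which may be technical or clonal.

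The podoplanin transcript (PDPN, ENSCAFG00000016363) was lower in every KO library than in the control of its line. In CMM2 it stood at 20.2 CPM in the control (212 counts), 5.59 CPM in KO 1 (64 counts) and 5.58 CPM in KO 2 (59 counts), so both KO lines kept 27.6% of the control level. In CMM12 the control had 87.8 CPM (1017 counts), KO 1 had 15.2 CPM (167 counts) and KO 2 had 9.98 CPM (102 counts), which is 17.4% and 11.4% of the control. Across lines the log2 fold change was −2.36 (SE 0.28), with an edgeR quasi-likelihood p of 4.7e-05 for the targeted gene alone. It ranked second of all genes by p, with a Benjamini-Hochberg adjusted p of 0.288 over all genes by edgeR and 4.2e-08 by DESeq2. Taken by line, PDPN changed by −1.86 (SE 0.35) in CMM2 and −2.80 (SE 0.34) in CMM12, with edgeR p over the targeted gene alone of 0.0014 and 1.1e-04. Over all genes the adjusted p was 1 by edgeR and 0.228 by DESeq2 in CMM2, where PDPN was not called, and 0.307 and 9.8e-06 in CMM12. The 2 effects differed by −0.94 (SE 0.51), with an edgeR p of 0.11 for the difference. A KO that shifts the reading frame need not remove the transcript, so these levels check the labels and do not measure the protein.

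**Figure D1:**
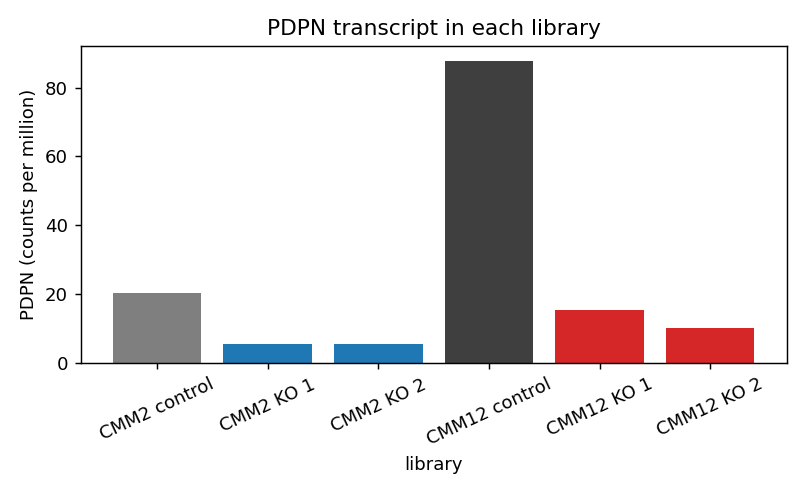
CPM of PDPN in each of the 6 libraries, 1 bar per library, grouped by cell line. The CMM2 KO bars sit at 5.59 and 5.58 against 20.2 in their control, and the CMM12 KO bars at 15.2 and 9.98 against 87.8.

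The comparison of all KO libraries with the controls, with the line as a block, asked which transcripts moved with podoplanin loss in both lines. By DESeq2, TAGLN, the actin-binding protein transgelin, rose by 2.26 on the log2 scale (SE 0.48), from 15.4 CPM in the CMM2 control to 53.8 and 121 in its KO lines, and from 33.5 to 204 and 67.6 in CMM12. FN1, which encodes fibronectin, rose by 0.78 (SE 0.16). The matrix glycoprotein gene FBLN1 rose by 1.53 (SE 0.36), and SEMA3A, a secreted guidance cue, by 1.43 (SE 0.31). ADCY3, an adenylate cyclase, changed by −4.21 (SE 0.75), from 98.0 CPM in the CMM12 control to 2.01 and 10.7, and from 2.48 CPM in the CMM2 control to 0 and 0.189. NEDD9, a scaffold of integrin signalling, changed by −3.61 (SE 0.86), from 17.7 CPM in the CMM12 control to 1.00 and 1.86, while CMM2 libraries had at most 0.191 CPM. DESeq2 adjusted p-values were 0.0051 for TAGLN, 0.0037 for FN1, 0.038 for FBLN1, 0.011 for SEMA3A, 6.7e-05 for ADCY3 and 0.041 for NEDD9. DESeq2 called 6 genes higher and 3 lower in KO, PDPN among them. The 2 not named so far, chosen after their values were seen, were PROM1, at 0 in every CMM2 library, and ENSCAFG00000003126, a gene without a symbol that had 0 and 1 counts in the controls and 218 to 909 in the KO libraries. edgeR's quasi-likelihood test called 0 of 12270 genes after Benjamini-Hochberg adjustment (smallest adjusted p 0.214). At an unadjusted p under 0.05 it had 495 genes, where chance alone would give 613.5, and limma on log2(TPM + 1) called 3. Without CMM12 KO 1 or without CMM12 KO 2 edgeR called ENSCAFG00000003126.

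Among the 40 gene lists fixed before the data were examined, 9 passed camera with a preset correlation across lines, 7 up and 2 down. No list passed with an estimated correlation, with adjusted p-values of 0.643 for the immediate early list and 0.605 for the other 8 lists with an estimated correlation, and these are given second below. Genes of the interferon response rose as a group, with 27 of 32 tested members higher (adjusted p = 0.00198, and 0.605 with an estimated correlation). OAS1 changed by 0.69 (SE 0.23), OAS2 by 0.83 (SE 0.32) and SAMD9L by 0.57 (SE 0.20). Immediate early transcription factors rose as a group (16 of 19 higher, adjusted p = 0.00201, estimated 0.643), among them EGR1 at 1.98 (SE 0.51) and KLF6 at 0.48 (SE 0.16). So did the feedback targets of ERK signalling (14 of 18 higher, adjusted p = 0.0023, estimated 0.605), with ETV1 at 0.88 (SE 0.26) and SPRY4 at 1.28 (SE 0.43). Proteases and other genes of invasion rose as a group (19 of 25 higher, adjusted p = 0.0023, estimated 0.605), with the cathepsin CTSK at 1.16 (SE 0.29), the collagenase MMP1 at 2.39 (SE 0.77) and the inhibitor TIMP1 at 1.71 (SE 0.56). Lysosome and autophagy genes rose as a group (23 of 28 higher, adjusted p = 0.00201, estimated 0.605), with CTSH at 1.06 (SE 0.40) and GAA at 0.51 (SE 0.22). Hypoxia and glycolysis genes also rose as a group (28 of 37 higher, adjusted p = 0.00673, estimated 0.605), with BNIP3 at 0.82 (SE 0.21) and CA9 at 0.54 (SE 0.20), and neural crest genes did (10 of 11 higher, adjusted p = 0.037, estimated 0.605), with the intermediate filament gene NES at 0.73 (SE 0.43). Nuclear genes of oxidative phosphorylation fell as a group (28 of 35 lower, adjusted p = 0.00329, estimated 0.605), with NDUFS1 at −0.48 (SE 0.17) and ATP5F1A at −0.45 (SE 0.18). The list of 4 neuronal and glial markers passed as down with 2 members lower and 2 higher (adjusted p = 0.037, estimated 0.605). Its largest change, that of the adhesion molecule NCAM1 at −5.84 (SE 0.90), rests on 27.0 CPM in the CMM12 control, against 0.730 and 0.0979 in its KO lines and 0 in every CMM2 library. fry passed 0 lists. No member of any list passed over all genes with edgeR, and 11 genes passed adjusted over the list alone, NCAM1 among them.

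Several of these list calls changed when 1 library was left out. Without a line's only control, the fit gives the KO effect of the other line alone. PDPN stood at −1.86 without the CMM12 control and −2.80 without the CMM2 control, its values in CMM2 and CMM12. In CMM2 camera put the immediate early and ERK lists as down, and neither passed (adjusted p 0.812 and 0.750). Their median changes in CMM2 were 0.08 and 0.03, with 10 of 19 and 9 of 18 members higher. Camera sets a list against the other genes, so its direction there shows no fall of these lists. Their rise across lines is that of CMM12. Without the CMM12 control the immediate early and ERK lists turned direction (adjusted p 0.832 and 0.760), and the interferon (0.0517), neural crest (0.0612), hypoxia (0.143) and neuronal (0.732) lists no longer passed. Without the CMM2 control the neural crest (0.276), protease (0.106), lysosome (0.192) and oxidative phosphorylation (0.153) lists no longer passed. Hypoxia genes lost their call without CMM2 KO 1 (0.0704), protease genes without CMM2 KO 2 (0.0812) and immediate early genes without CMM12 KO 2 (0.0903), while the neuronal markers lost theirs without CMM2 KO 2 (0.138), CMM12 KO 1 (0.0613) or CMM12 KO 2 (0.0744). The median change of the protease genes was 0.05 in CMM2 KO 1 and 0.61 in CMM2 KO 2, the library that stood apart, against 0.23 and 0.18 in the CMM12 KO lines. That of the interferon genes was 0.09 and 0.56 in the CMM2 KO lines and 0.46 and 0.54 in the CMM12 KO lines. With all libraries kept, camera on log2(TPM + 1) did not pass the neuronal (adjusted p 0.408) and neural crest (0.0898) lists. Its preranked form on the DESeq2 Wald statistics did not pass the neuronal list (0.379).

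**Figure D2:**
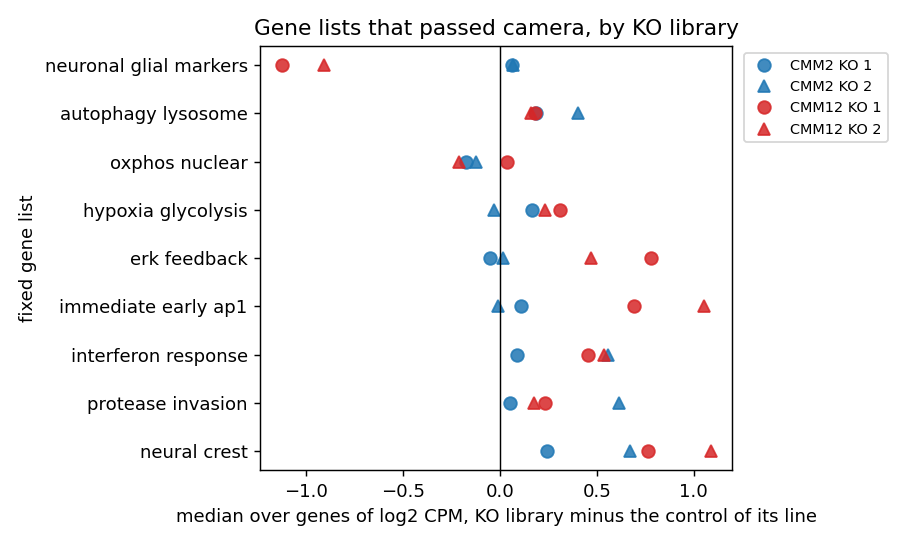
Median over each list's genes of the log2 CPM difference between a KO library and the control of its line, for the 9 lists that passed camera across lines, with circles for KO 1 and triangles for KO 2, CMM2 in blue and CMM12 in red. Interferon response genes lie at 0.09 and 0.56 in the CMM2 KO lines and at 0.46 and 0.54 in the CMM12 KO lines, while ERK feedback genes lie at −0.05 and 0.01 against 0.78 and 0.47.

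The list of podoplanin's binding partners did not pass (5 of 6 tested members higher, adjusted p = 0.0632, and 0.605 with an estimated correlation). CD44, the hyaluronan receptor, changed by 0.59 (SE 0.21) across lines. The ezrin-family genes MSN, EZR and RDX, which link membrane proteins to actin, changed by 0.39 (SE 0.25), 0.07 (SE 0.15) and −0.04 (SE 0.18). The galectin gene LGALS8 changed by 0.29 (SE 0.19) and the tetraspanin gene CD9 by 0.20 (SE 0.24). edgeR called none of the 6 (adjusted over the list alone 0, over all genes 0). CD44 had the smallest unadjusted p, 0.023.

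In CMM2 alone, TNS3 and TMLHE fell to 0 counts in both KO libraries. TNS3, a tensin of focal adhesions, stood at 6.21 CPM in the control and was at least 21.9-fold lower (DESeq2 adjusted p 0.0059), with folds against 0 taken at a floor of 3 counts per library. TMLHE, an enzyme of carnitine synthesis, stood at 3.72 CPM and was at least 13.1-fold lower (DESeq2 adjusted p 0.027). OLFML2B, which encodes an extracellular olfactomedin-domain protein, rose by 2.74 (SE 0.61, DESeq2 adjusted p 0.015), from 5.44 CPM to 18.4 and 54.3. LARP6, which binds collagen messenger RNAs, rose by 2.16 (SE 0.46, DESeq2 adjusted p 0.011), from 3.92 CPM to 15.6 and 19.4. DESeq2 called 3 genes higher and 3 lower, and the 2 not named so far, chosen after their values were seen, carry no symbol. They were ENSCAFG00000003126, with 0 counts in the control and 776 and 874 in the KO lines, and ENSCAFG00000000641, with 2049 counts in the control and 806 and 584 in the KO lines. edgeR's test called 0 genes (233 at an unadjusted p under 0.05, smallest adjusted p 1) and limma on log2(TPM + 1) called 0. Without CMM12 KO 1 or without CMM12 KO 2, edgeR called 1, ENSCAFG00000003126.

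Of the lists, 12 passed camera in CMM2, 9 up and 3 down. With an estimated correlation none passed (adjusted p = 0.658 for DNA replication and 0.644 for the other 11 lists with an estimated correlation), and these values are given second below. Semaphorin, ephrin and other guidance genes rose as a group (26 of 31 higher, adjusted p = 1.69e-04, estimated 0.644), with SEMA3F at 1.41 (SE 0.46) and SEMA3A at 1.36 (SE 0.45). Collagen and matrix genes rose as a group (21 of 30 higher, adjusted p = 5.44e-04, estimated 0.644). COL1A2 went from 156 CPM in the control to 871 in KO 1 and 3897 in KO 2, and COL3A1 from 226 to 628 and 4927, so the largest values lay in the library that stood apart. Lysosome and autophagy genes rose (25 of 28 higher, adjusted p = 5.44e-04, estimated 0.644), with CTSA at 0.81 (SE 0.31), and cholesterol synthesis genes rose (18 of 22 higher, adjusted p = 0.00172, estimated 0.644), with LSS at 0.83 (SE 0.29) and the regulator SREBF2 at 0.83 (SE 0.33). Targets of TGF-beta and BMP rose (15 of 25 higher, adjusted p = 0.00592, estimated 0.644), with ID3 at 1.95 (SE 0.50). Protease genes (adjusted p 0.0126), actomyosin genes (0.0304), invasive melanoma genes (0.0304) and fatty acid genes (0.0334) rose as groups as well (estimated 0.644 for each). DNA replication genes fell as a group (34 of 41 lower, adjusted p = 5.44e-04, estimated 0.658), with CDC6 at −0.44 (SE 0.25), as did oxidative phosphorylation genes (31 of 35 lower, adjusted p = 0.00395, estimated 0.644) and heat shock genes (12 of 16 lower, adjusted p = 0.0256, estimated 0.644), with HSPH1 at −0.55 (SE 0.23). fry passed 0 lists. No member passed over all genes, and 1 gene, TNS3, passed adjusted over the list alone. Guidance, collagen and lysosome genes kept their call in each of the 4 fits without 1 KO library. Each of these fits kept the lone CMM2 control, and leaving out a CMM12 KO library changes mainly the spread and the genes tested. Without CMM2 KO 2 the DNA replication (adjusted p 0.854), protease (0.649), invasive (0.430), cholesterol (0.430) and fatty acid (0.309) lists lost theirs. Without CMM2 KO 1 the actomyosin (0.387), TGF-beta (0.0975), oxidative phosphorylation (0.0700) and heat shock (0.0630) lists did, and the protease and TGF-beta lists also did without CMM12 KO 1 (0.121 and 0.133) or CMM12 KO 2 (0.101 and 0.105).

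In CMM12 alone, several receptor, matrix and signalling transcripts were far lower in both KO lines. IGF2BP1, an RNA-binding protein of growth control, was the gene that edgeR called, at −6.59 on the log2 scale (SE 0.46, adjusted p 0.042). It went from 118 counts in the control to 2 counts over both KO libraries, a ratio of 108 with a 95% counting interval of 29.2 to 901, which covers counting error only. COL12A1, a fibril-associated collagen chain, fell from 1293 CPM in the control to 81.6 and 49.8 (log2 −4.30, SE 0.37, DESeq2 adjusted p 4.2e-27). EPHB2, an ephrin receptor, fell from 94.3 CPM to 6.38 and 1.27 (DESeq2 adjusted p 9.8e-06). TIAM1, an exchange factor for Rac, went from 21.7 CPM to 0.182 and 0.391, and ENG, a co-receptor of TGF-beta, from 264 counts to 2 counts over both KO libraries, a ratio of 241 (counting interval 66.1 to 2003). DESeq2 adjusted p-values were 7.7e-07 and 7.2e-09. SFRP2, a secreted Wnt modulator, and the receptor gene ADGRG2 were at 0 in both KO libraries and at least 45.3-fold and 40.3-fold lower (DESeq2 adjusted p 0.018 and 0.043). FAM167A fell by 4.04 on the log2 scale (SE 1.08, DESeq2 adjusted p 0.049). All 8 genes of this paragraph were among the 58 transcripts of the CMM12 control that both CMM12 KO libraries had at 10% of its level or less, so each change rests on that control library.

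Genes that rose in CMM12 KO lines by DESeq2 included CDKN1A, the cyclin-dependent kinase inhibitor p21, from 2.59 CPM to 11.7 and 14.2 (log2 2.32, SE 0.45, adjusted p 0.00028). PROM1, the membrane protein prominin, rose from 1.98 CPM to 36.0 and 23.9 (log2 3.92, SE 0.78, adjusted p 0.00038). PTPRK, a receptor tyrosine phosphatase, rose from 9.92 CPM to 90.6 and 30.7 and MTSS1, an actin regulator, from 5.35 CPM to 31.6 and 54.4 (adjusted p 0.0064 and 0.014). The secreted hormone gene STC1 rose by 3.24 (SE 0.80), the inducible cyclooxygenase gene PTGS2 by 3.37 (SE 0.84), the anion transporter gene SLCO4A1 by 4.04 (SE 1.02) and the sodium channel subunit gene SCN2B by 3.52 (SE 0.89). DESeq2 called 21 genes higher and 24 lower in CMM12, while edgeR called IGF2BP1 alone (735 genes at an unadjusted p under 0.05, against 613.5 by chance) and limma on log2(TPM + 1) called 0. IGF2BP1 lost its edgeR call without CMM2 KO 1 (adjusted p 0.0512) or CMM2 KO 2 (0.124), with only the CMM12 libraries in the fit (0.239), with the stricter count filter (0.0567) and with limma (0.124 to 0.238). The edgeR count was 5 without CMM12 KO 1, where COL12A1, EPHB2, ENG and ENSCAFG00000003126 joined IGF2BP1, and 14 without CMM12 KO 2.

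**Figure D3:**
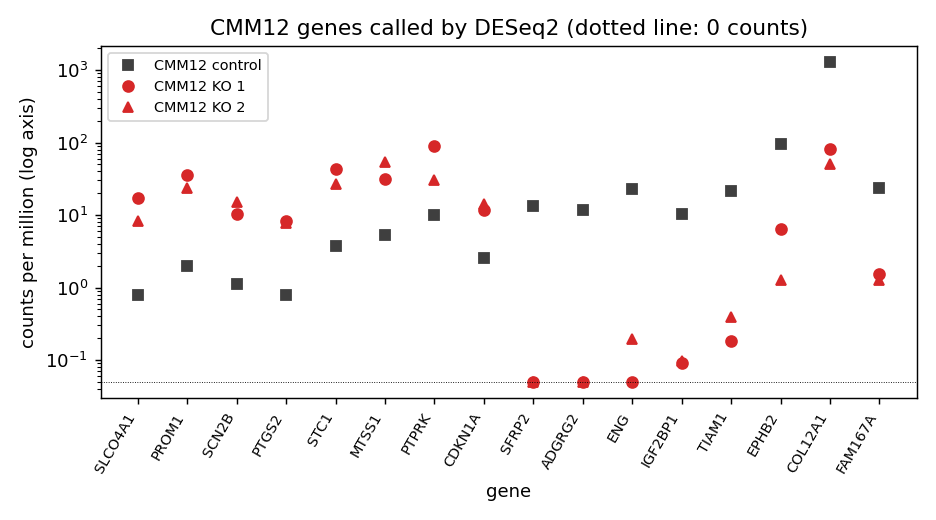
CPM, on a log axis, in the 3 CMM12 libraries for the genes named from the DESeq2 calls in CMM12, with squares for the control, circles for KO 1, triangles for KO 2 and a dotted line where libraries at 0 counts are drawn. COL12A1 lies at 1293 in the CMM12 control and at 81.6 and 49.8 in its KO lines, and CDKN1A at 2.59 against 11.7 and 14.2.

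In CMM12, 16 lists passed camera, 7 up and 9 down. No list passed with an estimated correlation (adjusted p = 0.550 to 0.682 with an estimated correlation), and these values are given second below. Feedback targets of ERK rose as a group (14 of 18 higher, adjusted p = 7.8e-06, estimated 0.550), with the ERK phosphatase DUSP6 at 1.45 (SE 0.26), DUSP5 at 1.26 (SE 0.31) and CCND1 at 0.89 (SE 0.25). Immediate early genes rose (17 of 19 higher, adjusted p = 1.23e-05, estimated 0.550), with FOS at 2.85 (SE 0.96) and EGR1 at 2.20 (SE 0.74). Mitosis genes rose (27 of 36 higher, adjusted p = 0.00904, estimated 0.650), with CENPF at 1.04 (SE 0.25), as did interferon genes (24 of 32 higher, 0.00731, estimated 0.550), hypoxia genes (26 of 37 higher, 0.0247, estimated 0.550), genes of the mitochondrial genome (11 of 13 higher, 0.0391, estimated 0.682) and heat shock genes (13 of 16 higher, 0.0464, estimated 0.550). Cholesterol synthesis genes fell (18 of 22 lower, adjusted p = 3.94e-04, estimated 0.620), with INSIG1 at −2.18 (SE 0.53) and DHCR7 at −1.02 (SE 0.32), and fatty acid genes fell (16 of 24 lower, 0.00904, estimated 0.550), with the desaturase SCD at −1.42 (SE 0.29). Collagen and matrix genes fell (18 of 30 lower, 0.00177, estimated 0.620), with COL1A1 from 680 CPM in the control to 5.56 and 73.4. Wnt pathway genes fell (24 of 30 lower, 0.0136, estimated 0.620), with the Wnt inhibitor DKK1 at −4.13 (SE 1.11). Epithelial genes fell (7 of 12 lower, 0.00572, estimated 0.550), with CLDN1 at −4.44 (SE 0.76) and KRT14 at −5.04 (SE 1.07), as did fibroblast and muscle markers (10 of 16 lower, 0.0326, estimated 0.550) and mesenchymal genes (11 of 16 lower, 0.0464, estimated 0.550). The neuronal and glial list passed as down with 2 of 4 members lower and 2 higher (0.00731, estimated 0.550). The invasive melanoma list passed as down (0.0318, estimated 0.550) with a mean of −0.54 but a median of 0.17, and 15 of its 27 members were higher. Adjusted over the list alone 23 genes passed, against 0 list members over all genes. fry passed 1 list, the ERK targets (adjusted p 0.0124). The ERK and immediate early lists kept their call in all 4 fits without 1 KO library. All 4 fits kept the lone CMM12 control, so they do not show how far the calls rest on it. Leaving out a CMM2 KO library changes mainly the spread and the genes tested. Without CMM12 KO 1 the other 14 lost theirs, with adjusted p-values of 0.214 for the cholesterol and interferon lists and up to 0.823 for the Wnt list. Without CMM12 KO 2 the hypoxia (0.103), invasive (0.263), mesenchymal (0.174), fibroblast (0.340) and neuronal (0.280) lists did. Without CMM2 KO 1 and without CMM2 KO 2 the neuronal (0.147 and 0.139), invasive (0.0657 and 0.0621), mesenchymal (0.0536 and 0.0537) and fibroblast (0.0503 and 0.0501) lists did, and without CMM2 KO 1 the heat shock and mitochondrial lists (0.0503 each).

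The test of the difference between the lines' KO effects asked which transcripts responded unequally. Cholesterol and fatty acid synthesis genes had a lower KO effect in CMM12 than in CMM2, with 18 of 22 and 18 of 24 members lower (camera adjusted p 2.75e-06 and 6.73e-04, and 0.720 for each with an estimated correlation). ERK feedback genes had a higher one (15 of 18 members higher, adjusted p 7.8e-05, and 0.720 with an estimated correlation). By DESeq2, ENG (log2 −8.15, SE 1.22, adjusted p 2.6e-07), TIAM1 (−7.13, SE 1.29, 9.1e-05), IGF2BP1 (−6.02, SE 1.23, 0.0014), EPHB2 (−4.96, SE 1.13, 0.012) and TGFB3, a TGF-beta ligand (−5.84, SE 1.43, 0.029), had lower effects in CMM12. IGF2BP1 stood at 59.1, 37.4 and 34.0 CPM in the CMM2 libraries, and TGFB3 went from 87.8 CPM in the CMM12 control to 7.11 and 19.3 but from 0.955 in the CMM2 control to 2.10 and 14.4. TNS3, at 0 in both CMM2 KO libraries and at 7.59, 7.02 and 16.4 CPM in CMM12, and the co-chaperone gene DNAJA4 (log2 2.19, SE 0.51, 0.014) had higher effects in CMM12. DESeq2 called 2 genes higher and 20 lower, while edgeR called 0 (471 at an unadjusted p under 0.05, smallest adjusted p 0.451) and limma on log2(TPM + 1) called 0. Without CMM12 KO 2, edgeR called COL1A1 as lower. In all, 13 lists differed by camera with a preset correlation, in a test added after the data had been seen. None differed with an estimated correlation (adjusted p = 0.720 with an estimated correlation), fry passed the ERK list (0.00992), and 9 genes passed adjusted over the list alone against 0 over all genes. Without CMM12 KO 1, 4 of the 13 lists kept their call.

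Across the 12270 genes the KO effects of the lines were uncorrelated, with Pearson's r at −0.0014 (95% interval −0.019 to 0.016) and Spearman's rho at −0.0082, where genes are not independent replicates. The lines shared no control library, and 48.4% of genes had the same sign in both. At an unadjusted p under 0.05 in both lines there were 43 genes. Of these, 10 were higher in KO in both lines, 6 were lower in both and 27 went opposite ways, where the product of the counts per line gave 4.18, 2.09 and 7.69. The effects of both lines come from 1 fit with 1 spread estimate per gene, so the excess in every direction is no test of agreement. The shared ones included FBLN1, SEMA3A, TAGLN and FN1, higher in both lines, and PDPN, ADCY3, IGF2BP1, MERTK and PTPRD, lower in both, chosen after their values were seen. PTPRD, a receptor tyrosine phosphatase, had 27 and 31 counts in the controls and 0 in all 4 KO libraries, at least 8.95-fold lower, with a DESeq2 adjusted p of 0.0796.

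**Figure D4:**
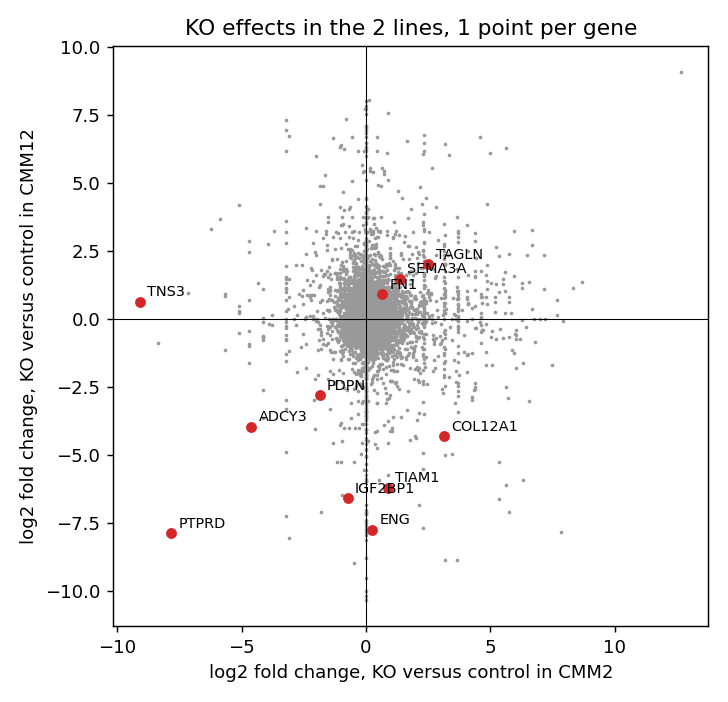
Log2 fold change of KO against control in CMM2 (horizontal axis) and CMM12 (vertical axis), 1 point per tested gene with some named genes in red, where fitted changes of genes at 0 in a group are no measured folds. Over 12270 genes Pearson's r is −0.0014, and PDPN lies at −1.86 and −2.80.

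CMM12 differed from CMM2, with the genotype as a block, in 3170 of 12270 genes by edgeR's quasi-likelihood test, 1792 higher and 1378 lower in CMM12. COL12A1 was again among the genes with the largest differences, with 16385 counts over the CMM12 libraries against 2 over the CMM2 libraries, a ratio of 8121 (95% counting interval 2248 to 67067). Of these counts 14981 lay in the CMM12 control and 895 and 509 in KO 1 and KO 2, and without that library the ratio was 1077. THY1, a surface glycoprotein of mesenchymal cells, was at least 958-fold higher in CMM12, the protease inhibitor TFPI2 at least 662-fold, the tubulin gene TUBA4A at least 501-fold, PDLIM4 at least 405-fold, CEP72 at least 266-fold, the itaconate-forming enzyme ACOD1 at least 153-fold and the protease inhibitor SPINT1 at least 143-fold. Lower in CMM12 were SNRPN, a splicing protein gene, by at least 238-fold, the actin regulator CAP2 by at least 106-fold, the Rac exchange factor PREX2 by at least 84.5-fold, KBTBD6 by at least 59.6-fold, the transcription factor PAX8 by at least 59.4-fold, GNA15 by at least 18.4-fold and GLIPR1L2 by at least 17.2-fold. INPP5D, a phosphatase of inositol lipids, had 878 counts in CMM2 against 2 in CMM12, a ratio of 443 (counting interval 122 to 3662). DESeq2 called 2170 genes higher and 1781 lower. The edgeR count was 1499 without CMM2 KO 1, 1680 without the CMM2 control, 1717 without the CMM12 control and 1690 without CMM12 KO 2. Against a fold of 1.5 it was 1329.

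By camera, 8 lists differed between the lines. No list passed with an estimated correlation (adjusted p = 0.756 for each of the 8 with an estimated correlation). Targets of TGF-beta and BMP were higher in CMM12 (8 of 25 members rose and 0 fell over all genes, adjusted p = 0.00439, estimated 0.756), with the activin subunit gene INHBA at 4.81 (SE 0.43), BMP4 at 4.05 (SE 0.50) and the BMP antagonist GREM1 at least 40.1-fold higher. Wnt pathway genes were higher (12 of 30 rose and 2 fell, 0.00563, estimated 0.756), with FZD6 at 1.55 (SE 0.16) and the Wnt deacylase NOTUM at 5.42 (SE 0.66), and so were epithelial genes (6 of 12 rose and 1 fell, 0.0187, estimated 0.756), with the junction gene JUP at 2.77 (SE 0.34) and the E-cadherin gene CDH1 at least 16.2-fold higher. Targets of p53 were lower in CMM12 (9 of 21 fell and 1 rose, 0.00439, estimated 0.756), with CDKN1A at −3.25 (SE 0.36), MDM2 at −1.25 (SE 0.15) and AEN at −2.33 (SE 0.15). DNA replication genes were lower (11 of 41 fell and 1 rose, 0.00563, estimated 0.756), with MCM4 at −1.53 (SE 0.16), as were cholesterol synthesis genes (7 of 22 fell and 1 rose, 0.0219, estimated 0.756), with FDPS at −1.03 (SE 0.16), and fatty acid genes (6 of 24 fell and 1 rose, 0.03, estimated 0.756), with ACSL5 at −5.46 (SE 0.35). Oxidative phosphorylation genes were lower (15 of 35 fell and 6 rose, 0.0358, estimated 0.756), although NDUFB5 (1.40), SDHC (1.45) and SDHA (1.18), among the members with the smallest p-values, rose. With fry, which sets a list against no change, 4 lists passed (adjusted p 0.0402 each), the TGF-beta, pigment and histone lists as higher in CMM12 and the unfolded protein list as lower. The pigment list did not pass camera (adjusted p 0.222, estimated 0.756). Of its 12 members 3 rose and 0 fell, the melanosomal enzyme TYRP1 by at least 16.4-fold and RAB38 by at least 29.8-fold among them. Adjusted over the list alone, members rose and fell in numbers of 10 and 1 (TGF-beta), 13 and 2 (Wnt), 8 and 1 (epithelial), 2 and 9 (p53), 1 and 11 (replication), 1 and 9 (cholesterol), 2 and 6 (fatty acid) and 6 and 19 (oxidative phosphorylation).

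KO 2 and KO 1 were also compared across lines, since the labels number the KO lines alike in both without saying whether the numbers stand for the same construct. SPON1, a secreted adhesion protein, was near absent in both KO 1 lines and present in both KO 2 lines, at 15.9 CPM in CMM2 and 13.2 CPM in CMM12, with 303 counts against 1 and a ratio of 327 (95% counting interval 58.2 to 12943). The controls had 16 counts in CMM2 and 84 in CMM12. ACTA2, smooth muscle actin, was lower in KO 2, at 5.68 and 0.946 CPM in KO 1 and KO 2 of CMM2 and 108 and 4.01 CPM in CMM12 (log2 −3.86, SE 0.62, DESeq2 adjusted p 1.8e-06). By DESeq2, SERPINB10 (log2 6.31, SE 1.25), FAM184B (3.87, SE 0.89), the retinoic acid binding protein CRABP2 (3.77, SE 0.79) and the immune checkpoint gene VSIR (3.29, SE 0.84) were higher in KO 2. CHSY3, a chondroitin synthase (−3.54, SE 0.58), the potassium channel gene KCNK10 (−2.96, SE 0.62), the carbonic anhydrase CA4 (−4.14, SE 1.05) and TDRD12 were lower. CA4 and TDRD12 rest on CMM2, with 302 and 165 counts in KO 1 and 25 and 0 in KO 2, since CMM12 had 6 and 4 counts in KO 1 and 0 in KO 2. DESeq2 adjusted p-values of the genes named after ACTA2 ran from 2.9e-06 for CHSY3 to 0.039 for CA4 and VSIR, with 0.011 for TDRD12. That of SPON1 was 0.00011. DESeq2 called 19 genes higher and 8 lower, and edgeR called 0 (560 at an unadjusted p under 0.05, smallest adjusted p 0.267). Without 1 KO library, a KO number rests on the library of 1 line, so such fits do not compare the numbers across lines. Their calls are not given. IL33, a cytokine gene that edgeR called without a low-count filter, was chosen after its values were seen. It had 1288 counts in CMM12 KO 1, 1 in CMM12 KO 2 and 52 in the CMM12 control, and 0 in every CMM2 library. DNA replication (38 of 41 lower) and ribosomal protein genes (31 of 32 lower) were lower in KO 2 as groups by camera (adjusted p 2.92e-06 and 3.98e-05), and guidance genes higher (24 of 31, 1.22e-04). These were 3 of the 14 lists that passed in a test added after the data had been seen, and none passed with an estimated correlation (adjusted p = 0.632 with an estimated correlation for these 3). Against the own control, the median change of the replication genes was 0.01 in CMM2 KO 1 and −0.46 in CMM2 KO 2, the library that stood apart, but 0.15 and 0.07 in the CMM12 KO lines. That of the ribosomal protein genes was −0.01 and −0.21 in CMM2 and 0.32 and −0.03 in CMM12, and that of the guidance genes 0.18 and 0.63 in CMM2 and −0.13 and −0.0028 in CMM12. fry passed 0 lists. Over all genes 0 list members passed with edgeR, and 5 did adjusted over the list alone.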

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

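Among the tests in this part, the one with an estimated correlation was chosen only after its result was seen, and so was testing gene lists for the difference between lines, while the tests without 1 KO library and with other library scaling were set before their results were seen. For 13 of the 40 gene lists the KO effect differed between CMM12 and CMM2 by camera with a preset correlation, and that difference between the lines is why they are listed. With an estimated correlation each of the 13 had an adjusted p of 0.720. The KO effect was lower in CMM12 for cholesterol synthesis (adjusted p 2.75e-06), collagen and matrix (0.000541), fatty acid and lipid (0.000673), guidance (0.00151), mesenchymal (0.0104), TGF-beta and BMP target (0.0104) and invasive melanoma genes (0.0201). It was higher in CMM12 for ERK feedback (7.80e-05), immediate early (0.000541), mitosis (0.00122), DNA replication (0.00251), heat shock (0.00315) and ribosomal protein genes (0.0201).

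Median-of-ratios size factors left all 13 lists with call and direction but moved the median of all genes only from −0.0128 to −0.00962, so library scaling stays open. A single KO library may decide many of these calls, since without CMM12 KO 1 only 4 of the 13 lists kept theirs, against 11, 9 and 10 without CMM2 KO 1, CMM2 KO 2 and CMM12 KO 2, with the direction kept by all 13 in each of the 4 fits. Members that vary together stay open, because the test with an estimated correlation cannot decide. It passed 0 lists here and 0 in the comparison of CMM12 with CMM2 with its 3170 called genes. For the ERK feedback list the unadjusted camera p was 3.9e-06 with the preset and 0.038 with the estimate, though its estimate lay below the preset 0.01. The ERK feedback list passed fry (adjusted p 0.00992), which sets a list against no change and not against other genes. The estimate was below 0 for the ERK feedback (−0.0518), TGF-beta and BMP target (−0.0411), heat shock (−0.0367), mesenchymal (−0.0211) and invasive melanoma lists (−0.0106), but it rests on 2 residual degrees of freedom. A different response of the cell lines to podoplanin loss stays open too, as each line has 1 control library and line and library cannot be separated further. CMM2 KO 2 and the CMM12 control, a KO and a control library, lay together on the second principal component. On the third they lay apart, at 32.0 and −41.0. How far either component bears on the 13 lists was not tested.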

How the results depend on the processing

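Over the named genes, lists and counts, alternatives left 11191 values labelled the same, 263 weaker, 104 stronger, 586 moved and 2 reversed. For a called result the same means that call and direction were kept, and for a count that it stayed within a factor of 1.5. For a gene that was not called it means a shift under its main SE, whatever the sign. Changes of sign among genes that were not called are therefore not counted as reversed. PDPN stayed lower in KO under all 19 alternatives across lines (log2 −2.80 to −1.86). The ends of that range are the fits without a line's only control, which give the KO effect of the other line alone. The genes taken by the rule for the largest edgeR changes between CMM12 and CMM2 kept call and direction under all 19 alternatives. These are the genes named above from COL12A1 to SPINT1 and from SNRPN to INPP5D. Members taken from the lists in that comparison are not covered by this statement. Across lines the edgeR count of 0 became 9 with DESeq2, 15 without a low-count filter, 3 with limma on log2(TPM + 1) and 2 on log2(TPM + 0.1), of which ENSCAFG00000029502 and ENSCAFG00000032016 had at most 4 counts in any library, and 0 to 1 on leaving out a library. In CMM2 the 0 became 6 with DESeq2, 1 without a filter and 1 with the line's libraries alone, ENSCAFG00000003126 in both, and 0 to 1 on leaving out a library. In CMM12 the 1 call became 45 with DESeq2, 26 without a filter, 0 with the stricter filter, 0 with limma under either pseudocount, 75 with limma without a filter, 0 with the line alone and 0 to 14 on leaving out a library. With the bias-adjusted fit, chosen after seeing the data, it became 4 (COL12A1, TNN, ENG and IGF2BP1). The difference between lines went from 0 to 22 with DESeq2, 2 without a filter (ENG and IGF2BP1) and 0 to 1 on leaving out a library. For CMM12 against CMM2 the 3170 calls became 1329 against a fold of 1.5 and 1499 to 3096 on leaving out a library. The share higher in CMM12, 56.5%, was 68.2% with limma on log2(TPM + 1), where the median change of all genes was 0.152 against 0.0382. For the KO numbers the 0 became 27 with DESeq2, 4 without a filter (SPON1, PLXNA2, IL33 and CHSY3) and 0 to 58 on leaving out a library. The 9 lists across lines became 0 with an estimated correlation and 9 to 16 on leaving out a library. Without the CMM12 control the immediate early and ERK lists reversed (signed −log10 p −0.0800 and −0.177, against highs of 6.18 and 6.71 on leaving out another library). The direction of these 2 lists is set against the other genes, and their own median changes in CMM2 were 0.08 and 0.03. The correlation of the lines' effects was −0.0258 on log2(TPM + 1) and −0.0890 to 0.0260 on leaving out a library. Fewer genes tested, fewer libraries or a stricter question are built into the filters, the fits without a library and the fold threshold. The cause was not tested for the others.

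With the KO number as a replicate block, 1 gene was called across lines, ADCY3, 12 lists passed, and the 4 KO libraries alone called 1700 genes between CMM12 and CMM2. The numbers are shared by 2 pairs, and the differences between KO 2 and KO 1 in the lines correlated at 0.061 across genes. By that correlation the block rests on a pairing that the values show little of. On the third principal component, however, KO 2 lay at 32.0 in CMM2 and 34.0 in CMM12, above KO 1 at −11.8 and 5.09. Whether same-numbered KO lines deviate together stays open.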

Other observations

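In this part, the tests on ENSCAFG00000003126 and on the CMM12 control were chosen only after the results were seen, while the splits of the libraries were planned.

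The CMM12 control carried 58 transcripts, at 20 or more counts, of which both CMM12 KO libraries had at most 10% of its level. They included genes of adhesion and matrix, namely NPNT (49.4 CPM in the control), TNN (26.3 CPM), the small proteoglycan LUM (16.9 CPM) and the laminin-binding integrin subunit ITGB4 (17.7 CPM). Epithelial genes were among them too, with KRT14 at 17.7 CPM and CLDN1 at 11.5 CPM, as were NCAM1 at 27.0 CPM and the melanosome transport gene MLPH at 4.92 CPM, all chosen after their values were seen. The 8 genes that the report names as lower in CMM12, from IGF2BP1 to FAM167A, were among the 58. The same count was 45 for CMM2 KO 2, the library that stood apart in its line, 22 for CMM12 KO 2, 8 for CMM12 KO 1, 6 for the CMM2 control and 1 for CMM2 KO 1.

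CMM2 cells in the CMM12 control are argued against as the source, since 26 genes counted in every CMM2 library and at 0 in both CMM12 KO libraries reached 0.457% of their CMM2 level there, under the 1% set as the bound. Cells of another type could bring such transcripts and stay open. Of the epithelial list, 58.3% of the 12 tested members were lower in both KO libraries, between the bounds of 80% and 50% set for this test. Fibroblast and neuronal markers stood at the lower bound, with 50% each. Endothelial markers, at 30%, and immune markers, at 16.7%, lay under it. The share over all genes was not computed. A difference between libraries or clones unrelated to podoplanin also stays open, because the highest count in another library, 45, is near the 58 of the control. Podoplanin loss itself cannot be told apart from these with 1 control library.

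ENSCAFG00000003126, a gene of 348 bp without a symbol, had 0 counts in the CMM2 control and 1 in the CMM12 control, but 776, 874, 909 and 218 counts in the 4 KO libraries. Its edgeR adjusted p across lines was 0.214 and its DESeq2 adjusted p 4.2e-08. No other choice of 1 library per line gave a gene at the floor in both and above 23 counts in each of the other 4 libraries. Reads taken from another listed gene may account for it and stay open, as 9 listed genes lost at least as many CPM in every KO library as this gene gained (at least 21.2 CPM), all of them abundant, among them NCL and HSP90AA1. Whether the sequence belongs to the KO construct was not tested.

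Genes counted in CMM12 libraries and at 0 in the CMM2 control and CMM2 KO 1 (132 genes) stood in CMM2 KO 2 at 0.664% of their CMM12 level.

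The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split of CMM12 against CMM2 called 3170 genes, as did 1 split in all, and the highest other called 0. Every other split mixes both lines in both groups, so the difference between lines enters its spread. The 0 is therefore no support for the 3170. The 9 choices of 1 library per line as the control are also too few. The real choice gave 495 genes at an unadjusted p under 0.05 across lines, and 5 choices, the real one included, gave at least as many. The highest other, with CMM2 KO 2 and the CMM12 control taken as controls, gave 1281. These libraries also lay together on the second principal component, but apart on the third, at 32.0 and −41.0. What produced the 1281 was not tested.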
